A study of Mus musculus with 27 samples.

How the data were processed

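Small RNA was measured in 3 subcellular fractions, chromatin, soluble nucleoplasm and cytoplasm, of 3 kinds of mouse cells. mESC is the E14 embryonic stem cell line grown with LIF. mNPC is a neural progenitor line that the depositing laboratory established and grew with EGF and FGF. mCtx are primary cortical neurons kept for 5 days in culture. Each of the 9 combinations of cell and fraction had 3 libraries, 27 in all. The labels call the libraries of a group biological replicates but do not state that they came from separate cultures, so the p values measure the spread between these libraries, which may be technical. Per the labels, RNA under 200 nt was depleted of rRNA, made into small RNA libraries of 120 to 160 bp and read as single reads of 100 bp. The fractions of one cell type had not been shown to come from the same cultures, and they were treated as unpaired.

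The deposited table gave each annotated small RNA in each library in RPM, reads scaled by the authors to a common library size. Each line of the table is called an entry here. There were 1013 entries: 483 of miRNA, 239 of snoRNA, 193 of tRNA, 34 of tRNA fragments, 27 of snRNA, 22 of rRNA and 15 of piRNA. A miRNA could have a hairpin entry and an entry for each mature arm. The aligner and the rule that assigned reads to entries are not given in the sources used here. Coordinates matched the mouse GENCODE annotation of the GRCm38 genome for 285 of the 288 entries with an Ensembl identifier, and all positions below refer to that genome. Of the snoRNA and snRNA entries, 115 and 22 carried only the name of a predicted gene, which begins with Gm.

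The values listed in a library summed to between 73.9% and 97.4% of the total that the unit implies. In every library there was a lowest value above 0, which ranged from 5.16 to 59.07 RPM, and everything under it was listed as 0. Read counts were not recovered. With the lowest value taken as 10 reads, between 53.8% and 67.7% of a library's low values came within 0.02 reads of a whole number. The exceptions were mESC nucleoplasm replicate 3 and mCtx chromatin replicate 2, at 4.2% and 4.9%. In most libraries the lowest value may thus stand for 10 reads. The depth was not given and was not worked out from this, so no counting intervals are given. A value of 0 is never read as absence of the RNA.

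Changes of single entries were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with an intensity trend and robust variance estimation. The 851 entries with at least 1 RPM in at least 3 libraries were tested. A mean was fitted for each of the 9 groups, leaving 18 residual degrees of freedom. The 20 contrasts were chromatin against cytoplasm, nucleoplasm against cytoplasm and chromatin against nucleoplasm in each cell type, the pairwise comparisons of mESC, mNPC and mCtx within each fraction, and a pair of interactions. The interactions asked whether the difference between chromatin and cytoplasm differed between mNPC and mESC, and between mCtx and mNPC. Within each contrast, p values were adjusted by the Benjamini-Hochberg method and an entry passed at 0.05. Levels are means ± SD of RPM over the 3 libraries of a group (n = 3); where a group held a 0, the libraries are given singly and no fold is stated.

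The share of each of 13 RNA classes in the listed reads of a library was compared by an exact permutation test, two-sided, on the mean over 3 strata of the difference in percentage points. Fractions were exchanged within cell types, and cell types within fractions. The 8000 assignments allow a smallest p of 0.00025, and p values were adjusted over the 39 tests of each kind. Fractions of one culture may not be independent, so the p values between cell types may be too small. The classes were the 7 deposited ones and 6 defined by gene name: C/D box snoRNAs, H/ACA box snoRNAs, scaRNAs, spliceosomal snRNAs, tRNAs with their fragments, and other named small RNAs.

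Lists of entries were tested with camera at a preset correlation of 0.01, and p values were adjusted over the 380 tests of 19 lists in 20 contrasts. The lists were all miRNAs, nuclear tRNAs with their fragments, C/D box snoRNAs, H/ACA box snoRNAs, spliceosomal snRNAs, other named small RNAs, the miR-290/295 cluster, the miR-17 family clusters, the let-7 and miR-125 family, neuronal miRNAs, neural progenitor miRNAs, the miRNAs and the snoRNAs of the imprinted Dlk1-Dio3 domain, the deposited snoRNA, snRNA and rRNA classes, and miRNAs of other cells in 3 lists: glia, microglia and blood, and endothelium and mesenchyme. The lists of scaRNAs, the miR-302/367 cluster, the Snurf-Snrpn snoRNAs and minor spliceosome snRNAs had fewer than 3 tested members and were not tested as lists. No entry matched mitochondrial tRNAs, embryonic or adult U1 genes, or Y and vault RNAs. The deposited classes were added to both families of tests after the table was seen, and the snoRNA lists of the imprinted domains were matched by coordinates then.

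The comparisons, the tests, the remaining lists and the rule for named entries were chosen before the data were examined. For a single pair of groups, the rule took entries past the threshold whose 3 libraries of one group all lay above the 3 of the other. Their mean in the higher group had to be at least 107 RPM, the median of tested entries. Chance gives such a separation in 10% of cases for 3 against 3 libraries. For interactions the rule asked for no separation, and the mean over all groups involved had to reach 107 RPM. From these the rule named the largest changes on each side: 4 between fractions, 5 between cell types and 3 for interactions. It named none for mCtx against mESC. From each list, the 4 most abundant members were added.

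The fits were tested on simulated data in which 200 of the 851 entries of the mESC chromatin and cytoplasm libraries were changed, 100 by 1 and 100 by 2 on the log2 scale. The fit recovered 44% and 76% of them among 147 calls, of which 27 were false (18.4%); the share planned as acceptable was exceeded. Of these false calls, 18 involved a 0 in some library. With every value raised to the highest library floor the fit made 113 calls, 11 of them false (9.73%), and recovered 37% and 65%. Means were simulated from values above 0, and spreads from groups without a 0. Entries that switch between 0 and high values, within a group or between hairpin and arm, were thus not simulated. The share of false calls in the real data may therefore differ. Camera called the raised list of 30 entries and 0 of 100 unchanged lists at an unadjusted 0.05. The simulated entries varied independently, so this cannot tell how often camera calls lists of correlated entries falsely. The permutation test gave p under 0.05 in 4.4% of 500 simulated sets without a difference and in 100% of 500 sets with a difference of 10 points at an SD of 3.

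Alternatives planned beforehand were pseudocounts of 0.1 and 10, no filter, a stricter filter keeping 426 entries, each library centred to the same median, only the groups compared, blocks of replicate number, leaving out each library in turn, shares on the log2 scale with 0.01% added, shares without the most abundant entry, an estimated correlation, and fry. Added after seeing the data were combined RNAs, a common floor and miRNA entries alone. Combined RNAs summed hairpin, arm and copy entries of one miRNA, tRNA entries of one anticodon, overlapping entries of one strand, and genes at least 90% identical with a length gap of at most 15 nt, giving 589 RNAs of which 519 were tested. The common floor raised every value to at least 59.07 RPM. The miRNA entries were rescaled to RPM of the miRNA reads alone. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out, and near-identical copies of an RNA, which may share reads, were kept as separate entries.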

Results

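The series followed where small RNAs are found in the cell, and in which form, as stem cells, neural progenitors and neurons were compared. Small RNAs were read from chromatin, nucleoplasm and cytoplasm of mESC, mNPC and mCtx, in 9 groups of 3 libraries. A library listed between 288 and 615 of the 1013 entries above 0. The lowest value listed above 0 lay between 45.18 and 54.8 RPM in mESC chromatin, 15.69 and 27.13 in mESC nucleoplasm, and 27.55 and 42.45 in mESC cytoplasm. In mNPC it lay between 32.48 and 59.07 RPM in chromatin, 30.17 and 34 in nucleoplasm, and 22.49 and 40.62 in cytoplasm. The mCtx libraries reached lower, to between 19.41 and 25.11 RPM in chromatin, 5.16 and 8.42 in nucleoplasm, and 8.4 and 18.63 in cytoplasm. Pearson's r between replicates, taken across entries, which are not independent replicates, ranged from 0.818 to 0.969.

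As shares of listed reads, chromatin held far more snoRNA and less miRNA than the other fractions. Such shares, like RPM, give no amount per cell. The values also do not tell full-length RNAs from shorter pieces of them. The libraries were 120 to 160 bp long, and the length of their adapters is not given. Levels listed under snoRNA, tRNA, snRNA and hairpin entries may thus be largely or wholly those of shorter pieces. snoRNAs, which guide the modification of rRNA and snRNA in the nucleus, made up 50.4% ± 4.52 of listed reads in mESC chromatin, 4.11% ± 1.92 in nucleoplasm and 0.391% ± 0.141 in cytoplasm (SD, n = 3). The corresponding snoRNA shares were 31.7% ± 8.57, 1.93% ± 0.323 and 0.052% ± 0.0204 in mNPC, and 22% ± 1.31, 1.37% ± 0.24 and 0.0564% ± 0.00505 in mCtx. miRNAs, the short guides of mRNA silencing, made up 27.5% ± 2.83, 80.8% ± 1.82 and 82.7% ± 4.28 of listed reads in chromatin, nucleoplasm and cytoplasm of mESC. Their shares were 62.9% ± 9.14, 94.7% ± 0.718 and 95.4% ± 0.338 in mNPC, and 74.4% ± 1.21, 95.9% ± 0.215 and 88.4% ± 0.662 in mCtx. The miRNA share outside snoRNA entries had chromatin to cytoplasm log2 ratios of -0.58 in mESC, -0.06 in mNPC and 0.11 in mCtx. Over all listed reads these ratios were -1.59, -0.6 and -0.25. Over the 3 cell types, chromatin exceeded cytoplasm by 34.5 percentage points in snoRNA, 1.24 in tRNA fragments and 1.14 in snRNA, and its miRNA share differed by -33.9 points, each in 3 of 3 cell types with an exact permutation adjusted p of 0.000424, the smallest that 8000 assignments could give. By name, C/D box snoRNAs differed by 21.5 points, H/ACA box snoRNAs by 0.674, scaRNAs by 0.0977 and other named small RNAs by 0.248, with the same exact permutation adjusted p.

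**Figure D1:**
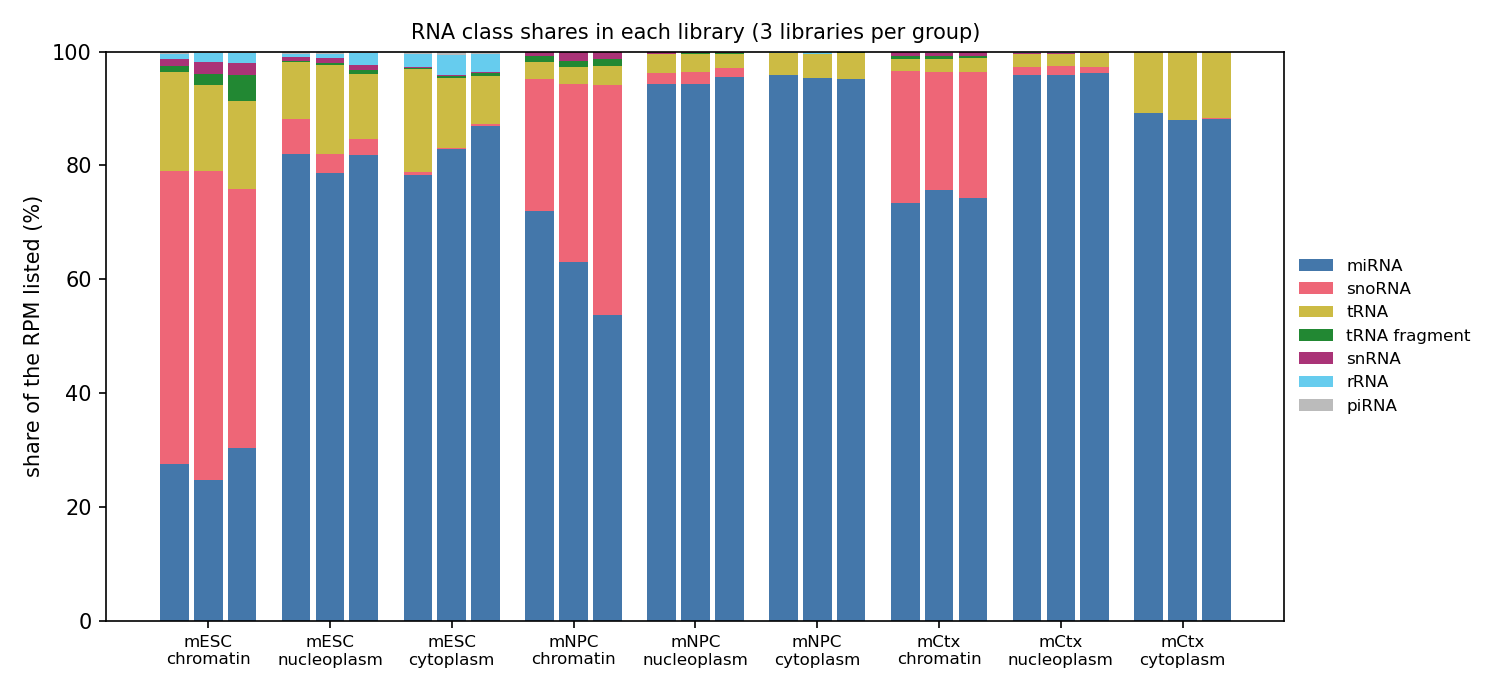
Stacked bars give the percent of listed reads (vertical axis) in each RNA class for each of the 27 libraries, grouped by cell type and fraction. Mean snoRNA shares in chromatin were 50.4% in mESC, 31.7% in mNPC and 22% in mCtx, against 0.391%, 0.052% and 0.0564% in cytoplasm.

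Nucleoplasm exceeded cytoplasm by 2.3 points in snoRNA and 0.331 in snRNA, while its miRNA share differed by 1.62 points and did not pass (exact permutation adjusted p of 0.000424, 0.000424 and 0.285). tRNA, the adaptor of translation, was lower in nucleoplasm by a difference of -3.65 points, in 3 of 3 cell types (exact permutation adjusted p = 0.0362). tRNA with its fragments differed by -3.57 points (0.0373 by the same test), and rRNA by -0.669, in 2 of 3 cell types (0.0311). Over 21 alternatives the adjusted p ran from 0.0156 to 0.116 for tRNA, 0.0165 to 0.117 for tRNA with fragments and 0.0217 to 0.225 for rRNA, and all 3 were lost when replicate numbers were used as blocks or without single libraries of nucleoplasm or cytoplasm. rRNA was also lower in chromatin than in cytoplasm by -0.575 points, in 2 of 3 cell types (exact permutation adjusted p = 0.00447), which became 0.0686 without mESC chromatin replicate 1, against a range of 0.00284 to 0.0686. Spliceosomal snRNAs by name were 0.103 points higher in chromatin than in cytoplasm (0.0195 by exact permutation, 0.0102 to 0.0508 over alternatives) and 0.0286 higher in nucleoplasm (0.00858). Between chromatin and cytoplasm, tRNA differed by -2.34 points, piRNA by -0.0599 and tRNA with fragments by -1.1, none past the threshold (exact permutation adjusted p of 0.203, 0.203 and 0.529). Against nucleoplasm, chromatin differed by 32.2 points in snoRNA, -35.5 in miRNA, 1.16 in tRNA fragments, 2.47 in tRNA with fragments and 0.805 in snRNA (each 0.000424 by exact permutation), whereas tRNA alone at 1.31, rRNA at 0.0942 and spliceosomal snRNA at 0.0746 did not pass (0.143, 0.738 and 0.064).

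Among single snoRNAs, Snord69, a C/D box RNA within Gnl3 (chromosome 14, 31014287 to 31014366), stood at 27240 ± 11500 RPM in mESC chromatin, 3044 ± 939 in nucleoplasm and 412.6 ± 13.7 in cytoplasm. Its chromatin and cytoplasm levels were 22420 ± 4420 and 144.5 ± 5.57 RPM in mNPC, and 5453 ± 146 and 30.13 ± 5.14 in mCtx. Snord69 was thus higher in chromatin by 5.93 on the log2 scale in mESC (SE 0.27), 7.25 in mNPC and 7.47 in mCtx (limma adjusted p of 8.77e-14, 3.5e-15 and 2.11e-15). Gm23201, a snoRNA in Zfas1 (chromosome 2, 167064998 to 167065086), Gm22455 in Rpl4, Gm24494 in Rabggtb and Snord14c in Hspa8 were the rises that the rule named in mESC chromatin. They stood at 8537 ± 1180, 7262 ± 1430, 7022 ± 606 and 6923 ± 350 RPM in chromatin and were listed at 0 in all cytoplasm libraries. Among others, the rule named Gm23212 in Gas5 (13610 ± 7930 RPM), Snord60 (8950 ± 3130) and Snord45c (5758 ± 1600) in mNPC chromatin, and Snord60 (3397 ± 380), Snord33 (2944 ± 357) and Snord90 (2619 ± 148) in mCtx chromatin, each listed at 0 in cytoplasm.

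The snoRNA class moved as a group. Of 196 tested snoRNAs, 150 rose and 2 fell in mESC chromatin against cytoplasm, 128 rose and 1 fell in mNPC, and 117 rose and 1 fell in mCtx. Adjusted over the list alone, 151 and 3, 128 and 1, and 121 and 1 passed. Camera gave adjusted p of 8.98e-45, 1.01e-38 and 4.01e-34. Of 74 C/D box snoRNAs recognised by name, 55, 50 and 52 rose and 0 fell, with 55, 51 and 54 up and 1, 0 and 0 down adjusted over the list alone (2.12e-17, 2.27e-19 and 3.21e-19 by camera). Of 18 H/ACA box snoRNAs, 15, 11 and 7 rose and 0 fell, with 16, 11 and 7 adjusted over the list alone. The H/ACA list had camera adjusted p of 5.93e-05, 0.00202 and 0.00714; for mNPC and mCtx the call was lost, at adjusted p = 0.0846 and 0.128 with an estimated correlation. All these lists kept their direction with each library centred to one median and with the common floor. Scarna9, a guide for snRNAs in Cajal bodies (chromosome 9, 15326264 to 15326333), had 685.9 ± 123 RPM in mESC, 1110 ± 204 in mNPC and 593.7 ± 81.1 in mCtx chromatin, and in cytoplasm its only value above 0 was 10.08 in mCtx.

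In all, limma called 463 of 851 entries between chromatin and cytoplasm of mESC (212 higher in chromatin, 251 lower), 330 in mNPC (164 and 166) and 375 in mCtx (172 and 203). Centring each library moved the share called higher from 45.8% to 15.9% in mESC and from 45.9% to 27.9% in mCtx. It shifted the median of all tested entries by between -4.49 and 5.67 on the log2 scale over the contrasts, and in 11 libraries that median was a value of 0. Values of 0 moved with the rest, so here and below entries at 0 could be called or turn direction through centring alone. Of the 463 mESC calls, 256 (55.3%) had a group listed entirely at 0. Among the 236 entries above 0 in all 6 libraries, 147 were called, 41 higher and 106 lower.

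Small nuclear RNAs were also found in chromatin. Rnu7, the U7 RNA of histone mRNA processing (chromosome 6, 124741225 to 124741286), had 1319 ± 237 RPM in mESC chromatin and 84.76 ± 17.1 in cytoplasm, a log2 difference of 3.95 (SE 1.15, limma adjusted p = 0.00587). Rnu7 had 825.1 ± 66.6 RPM in mNPC chromatin, against cytoplasm values of 0, 0 and 64.99, and 207.4 ± 56.4 in mCtx chromatin, against 0, 0 and 17.49. With Rnu73b and Rnu3a, the U3 RNA of rRNA processing, Rnu7 formed the list of other named small RNAs. Rnu73b and Rnu3a are themselves snoRNAs, so this list in part repeats the snoRNA result. In it 2 of 3 rose in mESC chromatin and 3 of 3 in mNPC and mCtx (3 and 3 adjusted over the list alone). Its camera adjusted p were 0.207, 0.00216 and 0.00535. Of 25 snRNAs, 6 rose and 3 fell in mESC chromatin against cytoplasm, 10 rose in mNPC and 16 in mCtx, with 10 and 16 adjusted over the list alone. The snRNA list passed in mNPC and mCtx (0.823, 0.00813 and 0.00234 by camera), but not at adjusted p = 0.192 and 0.13 with an estimated correlation. Among the 4 spliceosomal snRNAs recognised by name, 0 rose and 1 fell in mESC, and 2 rose in mNPC and in mCtx (camera adjusted p of 0.369, 0.273 and 0.156).

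Most miRNAs that changed between chromatin and cytoplasm were lower in chromatin. mmu-miR-22-3p (chromosome 11, 75463772 to 75463793) had 16380 ± 3610 RPM in mESC chromatin and 55070 ± 5930 in cytoplasm, a log2 difference of -1.77 (SE 0.25, limma adjusted p = 4.3e-06). In mNPC mmu-miR-22-3p had 23300 ± 8230 and 43140 ± 3130 RPM, differing by -0.95 (limma adjusted p = 0.00471), and in mCtx 18740 ± 808 and 28400 ± 10800, which did not pass (0.111). Of 418 tested miRNA entries, 12 rose and 195 fell in mESC chromatin, 12 rose and 99 fell in mNPC, and 23 rose and 106 fell in mCtx. Adjusted over the list alone, 12 and 194, 12 and 91, and 20 and 98 passed. Camera adjusted p were 4.74e-19, 1.7e-09 and 4.91e-05, the last becoming adjusted p = 0.163 with an estimated correlation. Scaled to miRNA reads alone, 89, 42 and 71 fell and 25, 15 and 42 rose, so that the share of calls that were higher moved from 5.8% to 21.9% in mESC, 10.8% to 26.3% in mNPC and 17.8% to 37.2% in mCtx.

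Among miRNA entries with the largest differences, hairpin and arm entries replaced one another. mmu-miR-21a-5p had 7921 ± 1670 RPM in mESC cytoplasm and was listed at 0 in mESC chromatin and nucleoplasm, where its hairpin entry mmu-mir-21a had 2364, 2765 and 0, and 13390 ± 717. With hairpin and arm summed, mESC chromatin was still called lower than cytoplasm (limma adjusted p = 0.0116), a call that rests in part on the library at 0. mmu-miR-93-5p had 6348 ± 1430 RPM in mESC cytoplasm and 0 in chromatin, and the summed difference was -1.58 (limma adjusted p = 5.45e-06). In mNPC chromatin mmu-miR-16-5p was listed at 0 while its hairpin mmu-mir-16-1 (chromosome 14, 61631880 to 61631972) had 16310 ± 4300 RPM. The hairpin was called higher in chromatin, but the sum of hairpin and arm was lower by -1.04 (limma adjusted p = 0.000508).

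**Figure D2:**
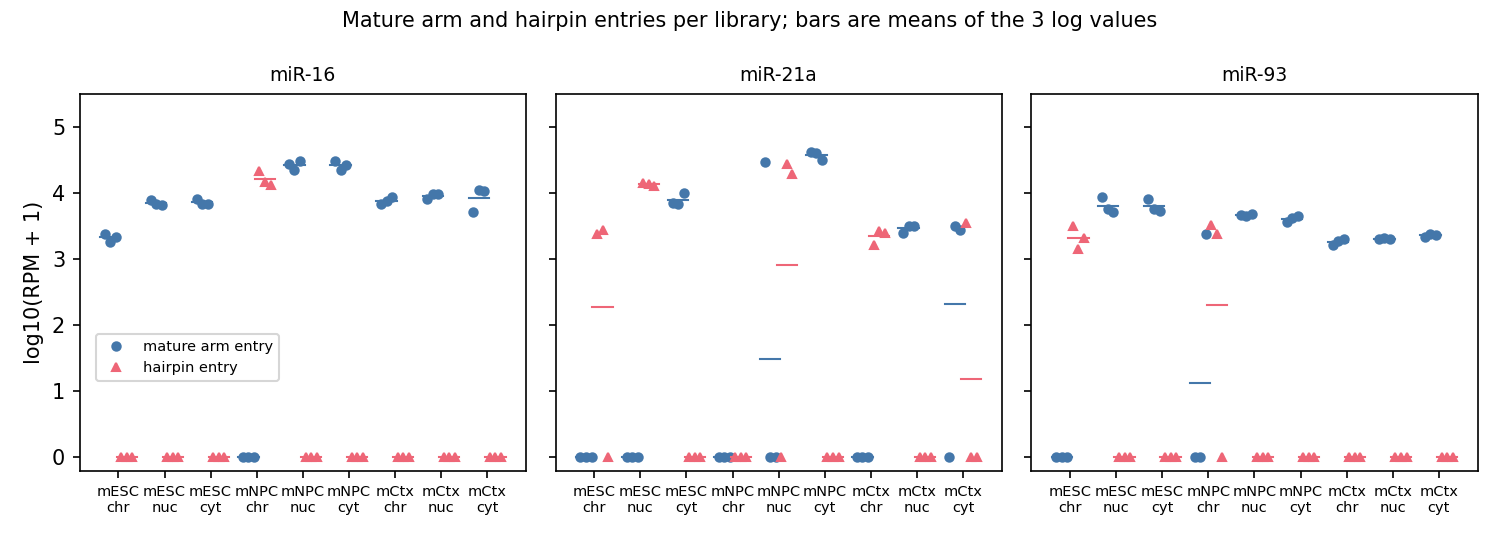
Points give the RPM of the mature arm entry and of the hairpin entry of miR-16, miR-21a and miR-93 (vertical axis, log10 of RPM + 1) in each of the 27 libraries. In mNPC chromatin the miR-16 arm was listed at 0 while its hairpin had 16310 ± 4300 RPM (SD, n = 3).

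tRNA-Val-CAC-2-1 (chromosome 1, 171111443 to 171111515), a tRNA for valine, had 7355 ± 1770 RPM in mCtx cytoplasm, 967.3 ± 76.7 in nucleoplasm and 608.6 ± 79.7 in chromatin. Its log2 difference between chromatin and cytoplasm was -3.57 in mCtx (SE 0.38), -2.64 in mNPC and -1.3 in mESC (limma adjusted p of 1.32e-07, 7.33e-06 and 0.00565), though in mESC the libraries of both groups overlapped. Of 187 tested entries of tRNAs and their fragments, 14 rose and 95 fell in mCtx chromatin against cytoplasm, and 14 rose and 61 fell in mNPC. Of the 28 fragments among them 9 rose and 0 fell in mCtx, and 7 and 1 in mNPC. The list had 14 and 98, and 14 and 61, adjusted over its members alone. Camera adjusted p were 4.97e-09 in mCtx and 0.00109 in mNPC, lost at adjusted p = 0.0664 and 0.336 with an estimated correlation. In mESC chromatin 43 rose and 44 fell (0.786). tRNA-Leu-CAA-3-1 was the largest named fall in mCtx chromatin, with 634.4 ± 69.3 RPM in cytoplasm and 0 in all chromatin libraries (limma adjusted p = 2.69e-07).

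Between nucleoplasm and cytoplasm, calls among snoRNAs were again mostly upward. Gm24494 and Gm22455 had 979 ± 285 and 547.8 ± 187 RPM in mESC nucleoplasm and 0 in cytoplasm, and Snord69 differed by 2.83 in mESC, 3.08 in mNPC and 4.14 in mCtx (limma adjusted p of 5.21e-08, 1.96e-08 and 1.06e-10). Of 196 snoRNAs, 71, 50 and 70 rose and 1 fell in mESC, mNPC and mCtx, with 76, 51 and 73 up and 1 down in each adjusted over the list alone (camera adjusted p of 1.97e-11, 1.01e-09 and 4.12e-14). In mESC this direction turned with centred libraries, where 13 rose and 43 fell. C/D box snoRNAs gave 31, 20 and 34 risen and 0 fallen, or 33, 21 and 38 adjusted over the list alone, but 6 risen and 12 fallen in mESC with centred libraries. Their camera adjusted p were 1.13e-07, 3.23e-06 and 6.34e-11, the mNPC value lost at adjusted p = 0.0636 with an estimated correlation. Of tRNAs and their fragments in nucleoplasm, 10 rose and 28 fell in mESC, 16 and 28 in mNPC, and 4 and 79 in mCtx, or 11 and 28, 16 and 29, and 4 and 95 adjusted over the list alone. This list passed in each (0.00013, 0.00491 and 1.67e-24 by camera), but in mESC and mNPC not at adjusted p = 0.251 and 0.421 with an estimated correlation. tRNA-Leu-CAG-2-1 had 26.71 ± 3.52 RPM in mCtx nucleoplasm and 319.6 ± 60 in cytoplasm, a log2 difference of -3.52 (SE 0.49, limma adjusted p = 1.27e-05); its near-identical copies share reads.

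miRNAs were split between nucleoplasm and cytoplasm: 30 rose and 10 fell in mESC, 8 and 21 in mNPC, and 30 and 19 in mCtx (camera adjusted p of 0.256, 0.0266 and 0.545; adjusted p = 0.478 in mNPC with an estimated correlation). In mNPC 6 snRNAs rose and 0 fell, and in mCtx 7 and 0 (0.00497 and 0.0447 by camera, or adjusted p = 0.168 and 0.344 with an estimated correlation). The spliceosomal list had 2 of 4 higher in mNPC nucleoplasm (0.0153 by camera, adjusted p = 0.0635 with an estimated correlation). In total 163 entries were called in mESC (119 higher in nucleoplasm, 44 lower), 132 in mNPC (80 and 52) and 215 in mCtx (115 and 100). With centred libraries 2.8% rather than 73% of the mESC calls and 22.1% rather than 53.5% of the mCtx calls were higher. With the common floor 50 were higher and 38 lower in mESC, 52 and 54 in mNPC, and 48 and 106 in mCtx.

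Chromatin and nucleoplasm differed in 432 entries of mESC (169 higher in chromatin, 263 lower), 237 of mNPC (144 and 93) and 273 of mCtx (127 and 146). The split depended on the treatment of low values: with the common floor mESC had 207 and 208 and mCtx 132 and 82, and with the stricter filter mCtx had 87 and 52. Snord104, a C/D box snoRNA (chromosome 11, 106500993 to 106501062), had 23960 ± 1930 RPM in mCtx chromatin, was listed at 0 in nucleoplasm and had 141.1 ± 57.9 in cytoplasm. Snord13 had 1585 ± 248 RPM in mCtx chromatin. Of 196 snoRNAs, 127 rose and 10 fell in mESC, 109 and 5 in mNPC, and 94 and 10 in mCtx, or 130 and 11, 110 and 5, and 100 and 10 adjusted over the list alone (4.01e-34, 8.97e-28 and 1.74e-23 by camera). Some snoRNAs were listed lower in chromatin: Gm22680 (chromosome 19, 8725341 to 8725409), within Snhg1, had 4132, 2326 and 1833 RPM in mESC nucleoplasm and 0 in chromatin. Gm24452 of the same host had 6948 ± 1970 in mESC chromatin and 0 in nucleoplasm. Within a single group, 45 of 239 snoRNA entries had both a value of 0 and a value at least 10 times the highest floor. Gm22680 did so in mNPC chromatin. For these entries and Snord104, assignment of reads to entries was not told apart from place in the cell. For miRNAs 12 rose and 215 fell in mESC chromatin, 11 and 59 in mNPC, and 7 and 110 in mCtx (1.67e-24, 2.24e-09 and 8.76e-14 by camera). Scaled to miRNA reads alone, the share of miRNA calls that were higher moved from 5.3% to 16.9%, 15.7% to 35.3% and 6% to 19.4%.

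**Figure D3:**
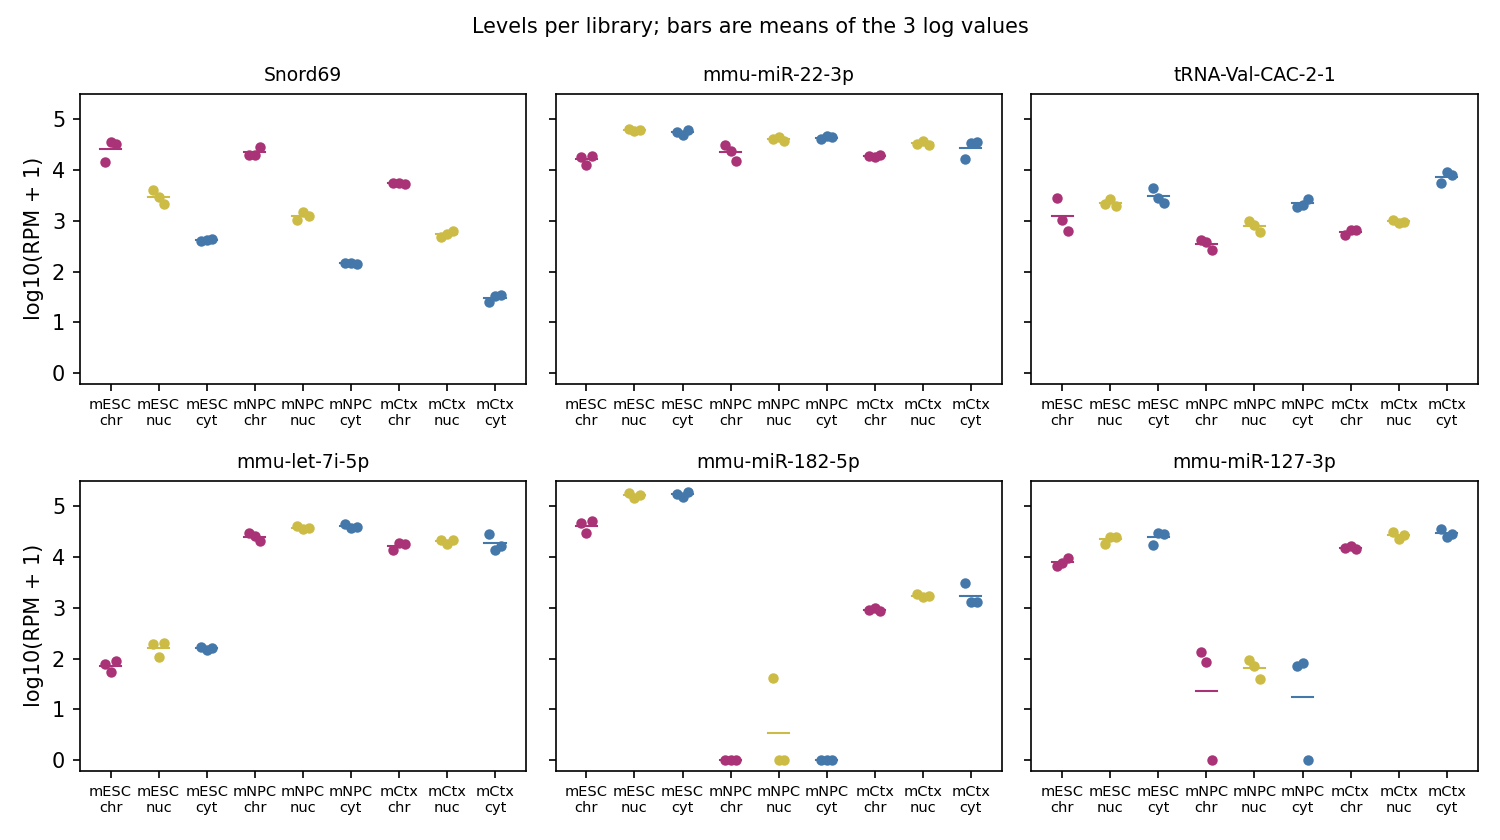
Points give the RPM of 6 small RNAs in each of the 27 libraries (vertical axis, log10 of RPM + 1) by cell type and fraction, and bars the mean of the 3 log values. Snord69 averaged 27240 RPM in mESC chromatin and 412.6 in cytoplasm, while mmu-let-7i-5p averaged 165.3 RPM in mESC nucleoplasm and 37350 in mNPC nucleoplasm.

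From mESC to mNPC, entries of the let-7 and miR-125 family, which is low in pluripotent cells and increases on differentiation, mostly rose. mmu-let-7i-5p (chromosome 10, 122985698 to 122985719) went from 72.82 ± 17 to 25010 ± 4820 RPM in chromatin, from 165.3 ± 51.6 to 37350 ± 2990 in nucleoplasm and from 159.2 ± 9.24 to 40360 ± 3940 in cytoplasm. These rises were 8.41, 7.86 and 7.97 on the log2 scale (SE 0.25; limma adjusted p of 3.81e-17, 1.27e-16 and 9.48e-17). Of 28 tested family entries, 18 rose and 1 fell in chromatin, and 21 rose and 0 fell in nucleoplasm and in cytoplasm, with 18 and 1, 21 and 1, and 21 and 0 adjusted over the list alone (7.3e-11, 3.28e-13 and 3.91e-13 by camera). mmu-miR-9-5p (chr3), a miRNA of neural progenitors and neurons, had 28420 ± 2750 RPM in mNPC nucleoplasm and 200.8 ± 36.1 in mESC nucleoplasm, and shares reads with its other copies. mmu-miR-181a-5p (chr1), also of several copies, had 50190 ± 10300 RPM in mNPC nucleoplasm and 154.7 ± 121 in mESC nucleoplasm. Among the largest named rises, mmu-miR-99a-5p had 2418 ± 169 RPM and mmu-miR-488-3p 1681 ± 239 in mNPC nucleoplasm.

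The miR-290 to miR-295 cluster, made in pluripotent cells, was found in mESC and listed at 0 in mNPC and mCtx for each of its most abundant members. mmu-miR-293-5p had 2989 ± 840, 15840 ± 1640 and 19540 ± 3080 RPM in chromatin, nucleoplasm and cytoplasm of mESC, and mmu-miR-292a-3p 4983 ± 1050, 7922 ± 1360 and 12350 ± 1390. Of 14 tested entries, 9, 13 and 13 fell in mNPC chromatin, nucleoplasm and cytoplasm and 0 rose, with 9, 14 and 13 adjusted over the list alone (9.8e-06, 9.85e-08 and 1.62e-09 by camera). mmu-miR-302a-3p, the tested member of the miR-302 and miR-367 cluster, had 18.83, 32.56 and 0 RPM in mESC nucleoplasm. mmu-miR-182-5p (chromosome 6, 30165962 to 30165986) had 42100 ± 11200, 161500 ± 18200 and 168500 ± 17000 RPM in mESC and in mNPC a single value above 0, of 40.73 in nucleoplasm. With mmu-miR-183-5p, at 13960 ± 1540 RPM in mESC nucleoplasm, it was among the largest falls. The neural progenitor list, which holds mmu-miR-9-5p and mmu-miR-182-5p, had 8 up and 4 down, 8 and 6, and 9 and 5 and did not pass (0.198, 0.232 and 0.327 by camera); in nucleoplasm its median was 2.53 and its mean -0.03. miR-17 family clusters, tied to proliferation, had 2 up and 11 down in chromatin, 0 and 13 in nucleoplasm, and 0 and 14 in cytoplasm, or 0 and 15 adjusted over the list alone there (0.334, 0.144 and 0.0355 by camera, the last adjusted p = 0.441 with an estimated correlation). Its mmu-miR-92a-3p (chr14), a copy that may share reads with the one on chromosome X, fell by 1.54, 1.49 and 1.74 on the log2 scale in chromatin, nucleoplasm and cytoplasm, from 17560 ± 3330 to 5256 ± 957 RPM in cytoplasm (limma adjusted p = 0.000597 there).

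From mESC to mNPC, tRNA-Lys-CTT-3-3 fell by 2.42, 2.55 and 1.94 on the log2 scale in chromatin, nucleoplasm and cytoplasm, from 4976 ± 1450 to 833.3 ± 131 RPM in nucleoplasm (limma adjusted p of 1.02e-05, 5.45e-06 and 0.000155). Of 187 entries of tRNAs and their fragments, 5 rose and 94 fell in chromatin, 4 and 87 in nucleoplasm, and 9 and 79 in cytoplasm, the first and last being 5 and 94, and 9 and 79 adjusted over the list alone. Camera adjusted p were 0.00028, 0.0922 and 0.013, both calls lost at adjusted p = 0.281 and 0.478 with an estimated correlation, and in chromatin the direction turned with centred libraries, where 63 rose and 4 fell. Of 14 rRNA entries, 7, 9 and 8 fell and 0, 0 and 1 rose, in the same numbers adjusted over the list alone (0.0139, 0.00736 and 0.00742 by camera, adjusted p = 0.304, 0.261 and 0.261 with an estimated correlation), whereas centred libraries gave 5 up and 5 down in chromatin and 3 and 2 in nucleoplasm. Rn18s-rs5 (chr17) 39846353, the longest entry of an 18S rRNA sequence, had 7299 ± 4270, 5538 ± 4770 and 15960 ± 4020 RPM in mESC chromatin, nucleoplasm and cytoplasm, and a single mNPC value above 0, of 247.8 in cytoplasm; the libraries had been depleted of rRNA.

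Over the 3 fractions, the miRNA share was 20.7 points higher in mNPC than in mESC, while snoRNA differed by -7.08, tRNA by -10.4, rRNA by -1.75, piRNA by -0.324, C/D box snoRNA by -4.55 and H/ACA box snoRNA by -0.352 (exact permutation adjusted p = 0.000513 for each). snRNA differed by -0.491 and tRNA fragments by -0.629 (0.000975 and 0.00975 by the exact permutation test). For scaRNA at 0.0129 and spliceosomal snRNA at 0.0659 the differences did not pass (0.104 and 0.144). Some calls depended on a library: tRNA fragments were lost without any of the mNPC chromatin replicates (up to 0.141 in a range of 0.00146 to 0.141), H/ACA likewise (up to 0.13, range 0.000487 to 0.13) and snoRNA without mESC chromatin replicate 2 (0.0582, range 0.000487 to 0.0582). limma called 382 entries in chromatin (135 higher in mNPC, 247 lower), 414 in nucleoplasm (109 and 305) and 354 in cytoplasm (120 and 234). With centred libraries the share called higher went from 35.3% to 88.8%, 26.3% to 93.6% and 33.9% to 48.6%. Of 418 miRNA entries 106 rose and 79 fell in chromatin (camera adjusted p = 6.94e-05, adjusted p = 0.17 with an estimated correlation), where the median was 0, and scaled to miRNA reads alone 86 rose and 101 fell. In nucleoplasm 95 rose and 149 fell, with a mean of -1.25 but an upward list test that did not pass (0.184).

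Small RNAs of the imprinted Dlk1-Dio3 domain were mostly listed at 0 in mNPC and abundant in mESC and mCtx. mmu-miR-127-3p (chromosome 12, 109592888 to 109592909) had 7890 ± 1390, 22590 ± 3830 and 24680 ± 6500 RPM in chromatin, nucleoplasm and cytoplasm of mESC, 68.21 ± 27.5 in mNPC nucleoplasm, and 14960 ± 1070, 26650 ± 3760 and 29170 ± 5270 in mCtx. Summed, the domain's miRNAs reached 94900 ± 24400 RPM in mESC cytoplasm, 115 ± 99.6 in mNPC and 86200 ± 21300 in mCtx. Of 58 tested, 27, 45 and 41 fell and 0 rose from mESC to mNPC in chromatin, nucleoplasm and cytoplasm, in the same numbers adjusted over the list alone (0.000316, 1.48e-09 and 6.34e-11 by camera). The chromatin call was lost at adjusted p = 0.179 with an estimated correlation. With centred libraries 26 rose and 13 fell there, although the domain's miRNAs summed to 26300 ± 4490 RPM in mESC chromatin and 118 ± 138 in mNPC chromatin. Centring moved the median of all tested entries by 4.32 on the log2 scale in this comparison. Entries listed at 0 in mNPC could thus come out as rises. From mNPC to mCtx 30, 51 and 46 rose and 0 fell, or 30, 52 and 47 adjusted over the list alone (1.63e-11, 8.59e-22 and 2.42e-18 by camera). Against mESC, mCtx had 14 up and 11 down, 8 and 17, and 10 and 16 (0.369, 0.976 and 0.436). Of the domain's 9 tested snoRNAs, 6 fell in mNPC chromatin and 7 rose from mNPC to mCtx chromatin, or 7 and 8 adjusted over the list alone (0.042 and 0.000945 by camera, the first adjusted p = 0.119 with an estimated correlation). Gm25854 among them (chromosome 12, 109686798 to 109686869) had 427 ± 172 RPM in mESC chromatin and 831.7 ± 183 in mCtx chromatin, and was listed at 0 in mNPC. In chromatin against cytoplasm 6 of the 9 rose in mESC, 0 in mNPC and 7 in mCtx, or 7, 0 and 8 adjusted over the list alone (0.00714 and 0.00134 by camera in mESC and mCtx).

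From mNPC to mCtx, mmu-miR-181c-5p, a miRNA enriched in neurons, went from 3996 ± 455 to 11560 ± 996 RPM in chromatin, 6048 ± 929 to 16250 ± 817 in nucleoplasm and 4913 ± 611 to 10370 ± 2780 in cytoplasm, by 1.53, 1.44 and 1.05 on the log2 scale (limma adjusted p of 2.79e-06, 6.67e-06 and 0.000262). Of 41 tested neuronal miRNAs, 17 rose and 2 fell in chromatin, 22 and 3 in nucleoplasm and in cytoplasm, or 18 and 4, 22 and 3, and 23 and 3 adjusted over the list alone. Camera adjusted p were 0.000663, 9.23e-05 and 0.000469, all lost at adjusted p = 0.131, 0.0872 and 0.122 with an estimated correlation, and with centred libraries 6 rose and 8 fell in chromatin and 5 and 14 in nucleoplasm. Against mESC the same list had 25 up and 1 down, 36 and 2, and 35 and 2 in mCtx, or 25 and 2, 36 and 2, and 35 and 3 adjusted over the list alone (2.85e-09, 1.24e-13 and 5.3e-13 by camera). mmu-miR-181a-5p (chr1) had 143400 ± 23000 RPM in mCtx nucleoplasm and 50190 ± 10300 in mNPC nucleoplasm, which did not pass (limma adjusted p = 0.518, or 0.554 with combined RNAs); with the common floor it did (0.00138). let-7 and miR-125 entries had 4 up and 1 down, 4 and 2, and 1 and 3 between mNPC and mCtx (0.892, 0.469 and 0.24 by camera), while mmu-let-7i-5p fell by 1.11 in cytoplasm (0.00152 by limma). miR-17 family entries had 1 up and 9 down in mCtx cytoplasm, the same adjusted over the list alone (0.00885 by camera, adjusted p = 0.321 with an estimated correlation). In nucleoplasm and cytoplasm the largest named rises were Dlk1-Dio3 miRNAs. Examples were mmu-miR-410-3p, at 0 in mNPC and 18500 ± 5640 RPM in mCtx cytoplasm, and mmu-miR-434-3p at 11950 ± 7840. In chromatin the named rises also held the mmu-miR-16-5p entries, whose direction turned when hairpin and arm entries were summed. mmu-miR-184-3p, at 422.2 ± 105 RPM in mNPC nucleoplasm and 0 in mCtx, was among the named falls.

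In the cytoplasm of mCtx against mNPC, 60 entries of tRNAs and their fragments rose and 10 fell, or 68 and 10 adjusted over the list alone. The camera adjusted p was 0.05 after rounding and just under the threshold before it, the call was lost at adjusted p = 0.599 with an estimated correlation, and with centred libraries 6 rose and 19 fell. tRNA-Val-CAC-2-1 rose there by 1.72 on the log2 scale, from 2214 ± 449 to 7355 ± 1770 RPM (limma adjusted p = 0.00106). In nucleoplasm 15 entries of this list rose and 20 fell, with a mean of 0.22, a median of 0 and a downward list test (camera adjusted p = 0.0198, adjusted p = 0.502 with an estimated correlation). As shares of listed reads, mCtx differed from mNPC by -3.41 points in snoRNA, -0.26 in tRNA fragments, -0.229 in snRNA, -0.159 in H/ACA box snoRNA and -0.0202 in scaRNA (exact permutation adjusted p of 0.00429, 0.000513, 0.00279, 0.00722 and 0.00722), with snoRNA, H/ACA box snoRNA and scaRNA lower in 2 of 3 fractions. Without single mCtx chromatin replicates the snoRNA, snRNA, H/ACA and scaRNA calls were lost, and over alternatives the adjusted p reached 0.191, 0.125, 0.129 and 0.123 from 0.000975, 0.00139, 0.00722 and 0.006. miRNA at 1.94 points, tRNA at 1.95 and C/D box snoRNA at -1.15 did not pass (0.545, 0.123 and 0.187). limma called 237 entries in chromatin (136 higher in mCtx, 101 lower), 288 in nucleoplasm (200 and 88) and 275 in cytoplasm (183 and 92). With centred libraries the share called higher went from 57.4% to 13.6%, 69.4% to 5% and 66.5% to 23.5%. With the common floor 109 were higher and 139 lower, 85 and 99, and 112 and 99.

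Between mCtx and mESC the entries called were 443 in chromatin, 444 in nucleoplasm and 387 in cytoplasm. mmu-miR-182-5p, at 1873 ± 976 RPM in mCtx cytoplasm, was lower than in mESC by a log2 difference of -6.6 (SE 0.85, limma adjusted p = 1.56e-06). let-7 and miR-125 entries rose, 21, 23 and 21 of 28 with 0 falling, in chromatin, nucleoplasm and cytoplasm. miR-17 family clusters had 2 up and 17 down in nucleoplasm and 1 and 19 in cytoplasm (0.00501 and 0.000121 by camera, adjusted p = 0.282 and 0.122 with an estimated correlation). The miRNA share was 22.6 points higher in mCtx, and snoRNA differed by -10.5, rRNA by -1.77, snRNA by -0.719, tRNA fragments by -0.889, C/D box snoRNA by -5.7 and H/ACA box snoRNA by -0.51 (exact permutation adjusted p = 0.000513 for each), and tRNA by -8.43 (0.00297 by the same test). Without each mCtx chromatin replicate the tRNA fragment and H/ACA calls were lost, at up to 0.0687 and 0.0598 over alternatives that began at 0.000487. With centred libraries the share of calls that were higher went from 43.8% to 56.2% in chromatin and from 40.1% to 60.5% in nucleoplasm.

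The difference between chromatin and cytoplasm itself differed between cell types for 262 entries of mNPC against mESC (161 more positive in mNPC, 101 more negative) and for 147 of mCtx against mNPC (52 and 95). For Snord69, above 0 in all 27 libraries, the difference was larger in mNPC than in mESC by 1.32 on the log2 scale (SE 0.38, limma adjusted p = 0.0121), and between mCtx and mNPC it did not pass (0.835). For tRNAs and their fragments 3 of 187 were more positive and 34 more negative in mCtx than in mNPC (0.00399 by camera, adjusted p = 0.421 with an estimated correlation). With centred libraries the share of more positive calls went from 61.5% to 93.4% for mNPC against mESC and from 35.4% to 19.2% for mCtx against mNPC. With the common floor 163 were more positive and 170 more negative for mNPC against mESC.

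miRNAs of other cells that a culture could hold were looked at in the same contrasts. Of 15 glial miRNAs, 6 rose and 2 fell from mESC to mNPC in chromatin, 5 and 3 in nucleoplasm, and 6 and 2 in cytoplasm (camera adjusted p of 0.152, 0.059 and 0.0643), and from mNPC to mCtx 3 and 4, 3 and 5, and 2 and 5 (0.92, 0.395 and 0.12). Of 8 microglia and blood miRNAs, 3 rose and 2 fell, 2 and 4, and 3 and 4 from mESC to mNPC (0.558, 0.827 and 0.98), and 0 and 0, 1 and 1, and 3 and 1 from mNPC to mCtx (0.762, 0.8 and 0.926). Of 11 endothelial and mesenchymal miRNAs, 0 rose and 3, 9 and 5 fell from mESC to mNPC (0.808, 0.109 and 0.155). From mNPC to mCtx 1, 7 and 5 rose and 0 fell, the nucleoplasm alone passing (0.784, 0.00736 and 0.395), at adjusted p = 0.149 with an estimated correlation, 7 adjusted over the list alone, and 0 up and 4 down with centred libraries. mmu-miR-143-3p, abundant in smooth muscle, had 137 ± 33 RPM in mNPC nucleoplasm and 3527 ± 308 in mCtx nucleoplasm, and also 4676 ± 968 in mESC nucleoplasm.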

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

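The tests of the snoRNA share, of the hairpin and arm entries and of the Dlk1-Dio3 domain were chosen only after the results were seen; the counts over other splits of the libraries were planned.

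These results were singled out because the difference between chromatin and cytoplasm was tested to differ between cell types. For mNPC against mESC 262 entries differed, and for mCtx against mNPC 147. Fraction labels were also exchanged within each cell type. The real labels were set beside distinct exchanges drawn at random from those possible, 100 in all. At least 262 calls came in 8 of 100 and at least 147 in 13 of 100, with highest other counts of 538 and 434. A split that exchanges chromatin and cytoplasm in a single cell type adds both fraction effects together, so these shares neither exclude chance nor speak for it. Where an entry is listed at 0 throughout a cell type, the tested difference only restates that between the fractions of the other cell type and says nothing on its place in the cell.

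Each comparison of a single pair of groups had 10 splits, too few for a share under 0.05, and the real one gave the most calls, 1 of 10. In mESC, mNPC and mCtx the calls, each with the highest other count, were 463 (50), 330 (13) and 375 (67) for chromatin against cytoplasm, 163 (25), 132 (8) and 215 (27) for nucleoplasm against cytoplasm, and 432 (8), 237 (18) and 273 (14) for chromatin against nucleoplasm. In chromatin, nucleoplasm and cytoplasm they were 382 (33), 414 (4) and 354 (2) for mNPC against mESC, 237 (20), 288 (1) and 275 (46) for mCtx against mNPC, and 443 (4), 444 (12) and 387 (22) for mCtx against mESC.

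The fitted values of the entries named by the rule rest on values of 0 and on the pseudocount, and are no folds. For mNPC against mESC they were 17.42 for Gm22680 (SE 3.15, limma adjusted p = 0.000214), 16.6 for Gm25313 (1.46e-05) and 15.04 for Snord99 (0.00235), and -12.91 and -12.89 for mmu-miR-16-5p (chr14) and mmu-miR-16-5p (chr3) (both 3.01e-18) and -10.87 for Gm24452 (0.00196). For mCtx against mNPC they were 14.52 for mmu-miR-16-5p (chr3) and 14.52 for mmu-miR-16-5p (chr14) (4.79e-19), 10.41 for AF357428 (0.0084), -14.69 for Gm22680 (0.00229), -13.96 for mmu-mir-16-1 (5.19e-19) and -11.06 for Gm23969 (0.000119). Gm22680 had 0, 14400 and 38150 RPM in mNPC chromatin and 0 in all chromatin libraries of mESC and mCtx, though its nucleoplasm values were above 0 in all 3 cell types. Snord99 had 0, 0 and 37540 RPM in mESC chromatin and 12130, 11540 and 36470 in mNPC chromatin. AF357428 had 0, 1590 and 1159 RPM in mESC chromatin, 0 in mNPC and 1361 ± 86 in mCtx chromatin. Gm23969 had 1653, 1491 and 3907 RPM in mNPC chromatin and 0 in mCtx chromatin. The Gm25313 call ended when its near-identical family was summed (5.17, limma adjusted p = 0.113; 6.22e-08 to 0.113 over alternatives). With entries summed the miR-16 calls ended too, at 0.73 for mNPC against mESC, where the sign turned (limma adjusted p = 0.0767; 7.9e-20 to 0.0767), and at 0.89 for mCtx against mNPC, where the sign of mmu-mir-16-1 turned (0.0544; from 5.83e-21 for the arm and 3.48e-21 for the hairpin). Snord99 was lost with only the groups compared (limma adjusted p = 0.0623; 1.19e-09 to 0.0623), as was Gm22680 for mCtx against mNPC (0.074; 1.08e-16 to 0.074), which was also lost with centred libraries (0.0576), and so was AF357428 (0.0667; 1.48e-09 to 0.0667). The cause was not tested, except that summing removes the change between entries.

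Lists that differed between cell types are given by their median fitted difference, with the median at the common floor beside it, since many members rest on values of 0. Dlk1-Dio3 snoRNAs were at 0 in all mNPC libraries, as were the most abundant members of the miR-290 to miR-295 cluster, and 3 Dlk1-Dio3 miRNA entries were above 0 in each mNPC fraction, so for these lists the values restate the fractions of mESC or mCtx. For mNPC against mESC the medians were 1.98 for Dlk1-Dio3 miRNAs (1.29 at the common floor; 25 more positive and 1 more negative; camera adjusted p = 2.29e-05, adjusted p = 0.114 with an estimated correlation) and -6.94 for Dlk1-Dio3 snoRNAs (-1.79; 0 and 4; 0.00102). They were 0.86 for miRNAs (0.37; 112 and 28; 0.000131, adjusted p = 0.188 with an estimated correlation), where miRNA reads alone gave 64 and 29. For snoRNAs the median was -0.89 (-0.63; 17 and 36; 0.000423, adjusted p = 0.258 with an estimated correlation), which turned to 1.67 with 16 and 4 under centred libraries. For tRNAs with fragments it was -0.65 (-0.49; 19 and 33; 0.0331, adjusted p = 0.551 with an estimated correlation), which turned to 1.9 with 22 and 2 under centred libraries. The snRNA list had 3.04 (0.48; 8 and 0; 0.0102), the miR-290 to miR-295 cluster 1.59 (1.25; 8 and 2; 0.015) and spliceosomal snRNAs 7.49 (1.6; 3 and 0; 0.0177), none kept with an estimated correlation (adjusted p = 0.209, 0.0892 and 0.0664). Scaled to miRNA reads alone the median of the miR-290 to miR-295 cluster was -0.14. For mCtx against mNPC the medians were 6.02 for Dlk1-Dio3 snoRNAs (2.02; 5 and 0; 2.28e-05), -1.15 for tRNAs with fragments (-0.35; 3 and 34; 0.00399, adjusted p = 0.421 with an estimated correlation) and -1.19 for Dlk1-Dio3 miRNAs (-0.02; 0 and 11; 0.0311, adjusted p = 0.46 with an estimated correlation).

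A first pattern was the lower miRNA share of chromatin, for which a candidate explanation is that snoRNA reads alone took a larger part of the chromatin libraries. Outside snoRNA entries, the log2 ratio of the miRNA share in chromatin to that in cytoplasm was -0.06 in mNPC and 0.11 in mCtx. Over all reads it was -0.6 and -0.25. The shares outside snoRNA were 91.82% ± 1.87 in mNPC chromatin and 95.48% ± 0.35 in cytoplasm. In mCtx they were 95.38% ± 0.09 and 88.49% ± 0.67 (SD, n = 3). Among these reads miRNA was thus still lower in mNPC chromatin than in cytoplasm, and higher in mCtx chromatin. Since miRNA made up most of these reads, the ratio could change little, so it does not decide the explanation in these cell types. In mESC the ratio was -0.58 against -1.59 over all reads, with shares outside snoRNA of 55.49% ± 1.33 and 83% ± 4.21. The snoRNA reads thus cannot be the whole cause there. Scaled to miRNA reads, which sets the miRNA totals equal, the 122 mESC entries above 0 in all 6 libraries had a median difference of 0.11, and 9 of them were lower against 91 before. Of the 89 mESC entries still lower so scaled, 89.9% were at 0 in at least 1 chromatin library, so the detection floor may add to that number. Besides snoRNA and miRNA, mESC listed mostly tRNA, at 16% ± 1.17 of all listed reads in chromatin and 13% ± 4.79 in cytoplasm. tRNA fragments had 2.53% ± 1.89 and 0.299% ± 0.154. As snoRNA took 50.4% of chromatin and 0.391% of cytoplasm reads, tRNA made up far more of the remaining reads in chromatin. Why it did so was not tested.

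Another pattern was the hairpin and arm entries of miR-16, miR-21a and miR-93, called between fractions in opposite directions. If reads were listed under the hairpin in some libraries and the arm in others, summing both should end the calls. Of 9 hairpin calls 88.9% turned or ended (7 turned, 1 ended), but the arm is mostly the more abundant, so a real change in the hairpin RNA could have turned them as well. Of 22 arm calls 27.3% did so (1 turned, 5 ended), which does not exclude assignment. Since the miR-16 hairpin was at 0 in all mESC libraries, summing could not end the miR-16 calls there. Most other kept calls shrank. Those of mmu-miR-21a-3p in mESC chromatin grew, from -4.64 to -5.4 against cytoplasm and from -4.37 to -6.17 against nucleoplasm. The hairpin alone was above 0 in 3, 11 and 5 libraries for miR-16, miR-21a and miR-93, the main arm alone in 24, 12 and 22, and both in 0, which is consistent with assignment, while unprocessed precursor in chromatin was not tested.

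A last pattern was the lower level of Dlk1-Dio3 miRNAs in mNPC than in mESC cytoplasm. The detection floor was argued against as the whole cause, since 90.2% of the 41 cytoplasm calls were kept (37 of 41) with every value raised to the highest floor. For a larger share of other miRNAs in mNPC, the 109 other miRNA entries above 0 in all 6 libraries had a median difference of 0.73 (interquartile range -0.63 to 1.89). The domain's 37 members above 0 in all mESC cytoplasm libraries fell by a median of 8.1 on the log2 scale, and all 58 tested by 7.01. These fitted values rest on values of 0. The 109 entries thus did not fall with the domain. They had to be above 0 in mNPC, however, so miRNAs that fell to 0 there were left out and this explanation is not excluded. Of all 418 tested miRNA entries 109 rose and 126 fell in mNPC cytoplasm, the 41 domain calls among the latter. A lower output of the whole imprinted domain in this mNPC line may account for the low level of its miRNAs: 100% of the 36 mNPC chromatin values of the domain's 12 snoRNA entries were at 0, against 11 of 36 in mESC chromatin. This remains a hypothesis found and tested on the same libraries, and whether it belongs to the line or to neural progenitors was not tested, as there was a single line.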

How the results depend on the processing

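Tests with entries of a single RNA combined, with a common floor and with miRNA entries alone were chosen only after the data were seen.

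Of 1638 class share values under alternatives, 1571 kept direction and side of the threshold; of 312 counts of changed entries 268 stayed within 1.5 times; and of 2282 values of named entries 2227 kept direction and side. The cause of the changes was not tested, except where fewer entries or libraries, or summed entries, make it. A pair of normalisations meant for tables of counts was not run, because the values are RPM. Depth was not given and was not worked out. Library floors, which in most libraries may stand for 10 reads, limit these results. The floors differed 11.4 times, and in the 20 comparisons 38.2% to 77.5% of calls had a group entirely at 0. On simulated values 18.4% of calls were false, or 9.73% with the common floor. The simulation left out entries that switch between 0 and high values, so it does not give the share of false calls here.

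With each library centred to the same median, counts of changed entries went from 463 to 704 (chromatin against cytoplasm), 163 to 508 (nucleoplasm against cytoplasm) and 432 to 229 (chromatin against nucleoplasm) in mESC; for nucleoplasm against cytoplasm and chromatin against nucleoplasm they went from 132 to 81 and 237 to 129 in mNPC, and from 215 to 86 and 273 to 117 in mCtx. For mCtx against mESC they went from 443 to 267, 444 to 243 and 387 to 237 in chromatin, nucleoplasm and cytoplasm; for mCtx against mNPC from 288 to 525 in nucleoplasm and 275 to 166 in cytoplasm; and for the differences between cell types from 262 to 122 and 147 to 26. Of the 463, centring kept 363, ended 89 and gave 37 the opposite sign, called or not. With the stricter filter (426 entries, so fewer tested) they were 296, 95 and 271 in mESC, and 211 and 139 for chromatin against cytoplasm and nucleoplasm in mCtx. For mCtx against mNPC they were 153, 152 and 134 in chromatin, nucleoplasm and cytoplasm, for mNPC against mESC 265 and 210 and for mCtx against mESC 257 and 211 in nucleoplasm and cytoplasm, and for the differences 150 and 65. With combined RNAs (519, so fewer tested) nucleoplasm against cytoplasm gave 100, 61 and 125 in mESC, mNPC and mCtx and chromatin against cytoplasm 221 in mCtx. Combined RNAs gave 245, 263 and 204 for mNPC against mESC and 284, 279 and 212 for mCtx against mESC in chromatin, nucleoplasm and cytoplasm, 168 for mCtx against mNPC in cytoplasm, and 160 and 78 for the differences. The common floor gave 88 for nucleoplasm against cytoplasm in mESC and 184 for mCtx against mNPC in nucleoplasm, and only the groups compared 97 for the former. Scaled to miRNA reads alone, 5 of 20 counts of miRNA entries moved over 1.5 times. Testing all entries and pseudocounts of 0.1 and 10 moved 0 of 20 counts. Among 144 values of named entries, combined RNAs ended 12 besides those that turned, only the groups compared 8, and centring, the common floor and the pseudocount of 0.1 ended 3 each.

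Summing a miRNA's entries turned 10 values: mmu-miR-21a-5p to 0.77 (nucleoplasm against cytoplasm, mESC; limma adjusted p = 1), mmu-mir-93 to -1.57 (chromatin against nucleoplasm, mESC; 7.24e-06), mmu-mir-16-1 to -1.04 and -1.06 (chromatin against cytoplasm and nucleoplasm, mNPC; 0.000508 and 0.000581), mmu-mir-21a to -0.4 (chromatin against nucleoplasm, mCtx; 1), mmu-miR-16-5p (chr14) and mmu-miR-16-5p (chr3) to -0.75 (mCtx against mNPC, chromatin; 0.01), and in the differences between cell types both to 0.73 (0.0767) and mmu-mir-16-1 to 0.89 (0.0544).

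Of 380 list tests 133 were called; an estimated correlation called 55 and ended 78 (adjusted p of the 133 from 0.000278 to 0.599). The rotation test fry called 259, kept 128, ended 3 and gave 3 the opposite direction, called or not (3.88e-27 to 0.827); combined RNAs kept 101 (3.8e-47 to 0.469).

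Replicate numbers were not shown to pair the libraries: over 18 pairs of groups correlations ran from -0.12 to 0.19, and in 28 of 54 comparisons a library correlated best with its own number, against 18 by chance (16 of 27 between fractions of one cell type). That leans towards some pairing, but 0 pairs of groups had all 3 correlations above 0.1. The lean came from mESC and mNPC, each with 2, 3 and 2 best matches of 3 over its pairs of fractions. In mCtx these were 0, 0 and 2. As a replicate block the replicate numbers moved no count of entries over 1.5 times and kept all 133 list calls (5.55e-45 to 0.0488). By exact permutation within the block, 4 shares passed no longer, spliceosomal snRNA between chromatin and cytoplasm (0.103, adjusted p = 0.0508; 0.0102 to 0.0508 over alternatives) and, between nucleoplasm and cytoplasm, tRNA (-3.65, 0.116; 0.0156 to 0.116), tRNA with fragments (-3.57, 0.117; 0.0165 to 0.117) and rRNA (-0.669, 0.0979; 0.0217 to 0.225). tRNA fragments there (0.0762, 0.00635; 0.00635 to 0.488) and scaRNA in mNPC against mESC (0.0129, 0.042; 0.0209 to 0.217) came to pass. With log2 shares, between nucleoplasm and cytoplasm tRNA fragments passed (0.718, exact permutation adjusted p = 0.038) and rRNA did not (-1.03, 0.225), nor did snoRNA in mCtx against mNPC (-0.276, 0.136; 0.000975 to 0.191). Without the most abundant entry scaRNA in mNPC against mESC passed (0.015, exact permutation adjusted p = 0.0418) and snoRNA in mCtx against mNPC did not (-2.93, 0.191).

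Leaving out single libraries changed 0 of 132 counts, 16 of 915 values of named entries (in 4 entries) and 56 of 1404 class shares (in 17 of 78 results), the last given here as ranges with the highest exact permutation adjusted p. Nucleoplasm against cytoplasm lost tRNA (-4.39 to -2.8; 0.08) and tRNA with fragments (-4.28 to -2.75; 0.0806) without mESC nucleoplasm 1 or 3, mESC cytoplasm 1 or any one nucleoplasm or cytoplasm library of mCtx, and rRNA (-0.821 to -0.57; 0.13) without mESC nucleoplasm 1 or 2 or any one mESC cytoplasm library. With any one mNPC chromatin library left out mNPC against mESC lost tRNA fragments (-0.875 to -0.274; 0.141) and H/ACA snoRNA (-0.468 to -0.288; 0.13). With any one mCtx chromatin library left out mCtx against mESC lost H/ACA snoRNA (-0.626 to -0.446; 0.0598) and tRNA fragments (-1.14 to -0.535; 0.0687), and mCtx against mNPC lost snRNA (-0.29 to -0.189; 0.125), scaRNA (-0.0249 to -0.0174; 0.123), H/ACA snoRNA (-0.203 to -0.133; 0.129) and snoRNA (-4.8 to -1.95; 0.129). rRNA between chromatin and cytoplasm (-0.695 to -0.477) was lost without mESC chromatin 1 (0.0686), and snoRNA in mNPC against mESC (-8.55 to -5.69) without mESC chromatin 2 (0.0582). Shares that came to pass were spliceosomal snRNA (0.0543 to 0.0902) between chromatin and nucleoplasm without mESC chromatin 1 or 3 or mCtx chromatin 1, tRNA there (0.901 to 1.86) without mESC nucleoplasm 2, scaRNA in mNPC against mESC (0.0101 to 0.0176) without mESC nucleoplasm 1 or mNPC chromatin 1, and C/D snoRNA in mCtx against mNPC (-1.77 to -0.422) without mNPC chromatin 1. The named entries were mmu-miR-21a-5p between mNPC nucleoplasm and cytoplasm, without mNPC nucleoplasm 2 or 3, and tRNA-Leu-CAG-1-1, tRNA-Leu-CAG-1-2 and tRNA-Leu-CAG-1-3 between mCtx nucleoplasm and cytoplasm, without single libraries of either group.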

Other observations

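None of the tests here was chosen only after its result was seen, the prediction for the less abundant miRNA arms having been written first, but the RNAs named were chosen after their values were seen.

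Snord64, a C/D box snoRNA of the imprinted Snurf-Snrpn domain (chromosome 7, 59978808 to 59978874), was highest in neurons. It had 3781 ± 46.6 RPM in mCtx chromatin, 483.6 ± 57 in nucleoplasm and 24.42 ± 11.1 in cytoplasm, and 773 ± 197 in mNPC and 238.7 ± 112 in mESC chromatin (SD, n = 3). Snord64 rose by 4.09 on the log2 scale in chromatin from mESC to mCtx (limma adjusted p = 0.000659), but the difference from mNPC, 2.32 with an SE of 0.91, did not pass (0.0631). Snord107 of the same domain had 83.27 ± 10 RPM in mESC and 68.13 ± 18.3 in mCtx chromatin.

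Rnu12, the U12 RNA of the minor spliceosome (chromosome 15, 83149644 to 83149794), was highest in nucleoplasm in each cell type. It had 356.5 ± 78.2 RPM in mCtx nucleoplasm, 153 ± 24.1 in chromatin and 0 in cytoplasm; in mNPC it was listed above 0 in nucleoplasm alone, at 179.1 ± 43.7. In mESC it had 129.8 ± 4.46 RPM in nucleoplasm and 87.32 ± 26.2 in cytoplasm and 0 in chromatin. Rnu11, the U11 RNA, had 434 ± 294 RPM in mNPC chromatin. mmu-miR-34c-5p, known from multiciliated cells, rose from 538.6 ± 234 RPM in mESC to 4528 ± 532 in mNPC cytoplasm and fell to 62.07 ± 18.8 in mCtx, by 3.17 and -6.21 on the log2 scale (SE 0.35, limma adjusted p of 1.76e-07 and 5.46e-12). mmu-miR-150-5p, known from lymphocytes, had 2135 ± 298 RPM in mESC cytoplasm and 0 in mNPC and mCtx, and mmu-miR-126a-5p, known from endothelium, 1045 ± 192 in mESC, 114.5 ± 20.7 in mNPC and 101.3 ± 29 in mCtx cytoplasm.

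A hypothesis was that the less abundant arm of a miRNA is relatively more abundant in chromatin. Of 98 arm pairs looked at, 7, 4 and 4 were abundant enough in mESC, mNPC and mCtx, and the mean difference between chromatin and cytoplasm in the median log2 ratio of the minor to the major arm was -0.30 (exact permutation p = 0.36, the smallest possible being 0.00025). By cell type it was 0.88 in mESC, where 6 of 7 miRNAs were higher in chromatin, -1.81 in mNPC, with 0 of 4 higher, and 0.01 in mCtx. The mean thus averaged opposite directions, which were not tested singly, and the question stays undecided.

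In 102 cases an entry had, within 1 group, both a value of 0 and a value at least 10 times the highest library floor. These cases fell in 82 entries, with 57 of them in 45 snoRNA entries and 17 in 14 miRNA entries.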
